A study of Mus musculus with 2 samples.

How the data were processed

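Adrenal glands of 2 female B6CASTF1/J mice aged 36 days were profiled by total RNA-seq, with 1 library per animal. Per the labels, each library was made from 300 ng of RNA after ribosomal RNA reduction with a directional kit and ERCC spike-ins. The labels number the libraries as biological replicates 1 and 2 of 1 group. Per the labels, the sample characteristics give the animals different numbers, but the library descriptions give both the same number, and both carry the same donor identifier. The libraries were treated as 2 animals. If they shared an animal, the SDs and the biological coefficient of variation would measure only the spread between libraries. The tissue, strain, sex and age were the same, so there was no comparison of conditions, no test between groups and no biological explanation in the design.

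For each library there was a gene table and 2 transcript tables. Per the file headers, the gene table and the alignment-derived transcript table hold an expected count and TPM, and the text beside the deposited files states mm10, GENCODE M21 and a transcriptome alignment as their source. The column names are those that RSEM writes. The read-derived transcript table, per the file headers, holds an estimated count and TPM with the column names that kallisto writes, and was derived straight from the reads. The deposited expected counts are not all whole numbers, so reads that fit several genes can be divided among them. The deposited TPM sum to a fixed total over all entries, spike-ins and mitochondrial genes included, so TPM depends on the small RNAs that each table counts. The deposited bounds of the TPM interval were read as a signal, of a level not given in the sources used here. The deposited isoform percent is the share of a gene's TPM in a transcript. Here the shares were computed from TPM. The aligner, tool versions and filters are not given in the sources used here, nor whether the counting used strand, so antisense and overlapping genes are reported as uncertain.

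Gene symbols, biotypes and coordinates were taken from GENCODE M21 on mm10, which matches the stated annotation. Where a symbol had more than 1 record, the one with the higher mean TPM was used in lists. The tables held 97 control sequences, 96 of them ERCC, and 26248 tRNA entries with 3.88 and 2.81 expected counts in replicates 1 and 2. Neither entered the gene counts.

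Total expected counts were 35684781 in replicate 1 and 38701795 in replicate 2. Totals in the read-derived table were 34946406 and 37598352. A count of 0 was taken to allow 3 counts. Exact 95% intervals are Clopper-Pearson. Intervals and floors cover counting error only, since the reads carry no stated molecular identifiers.

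A gene was detected at 1 TPM or more in both animals. Levels are means and SDs over the animals. Correlations used log2(TPM + 1) over genes at 1 TPM or more in either animal. Ratios are replicate 2 over replicate 1 of TPM + 0.1, among genes with 200 or more summed counts for the count of genes 2-fold apart. Counting noise was simulated by binomial splitting in 100 draws. The biological coefficient of variation came from edgeR 4.0.16 in R 4.3.3, with an intercept-only design, TMM scaling and expected counts rounded to whole numbers, over genes with 10 or more counts in both libraries. DESeq2 1.42.0 gave alternative size factors. Tables were handled in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures drawn with matplotlib 3.10.9.

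For each of 31 gene lists, the median log2 ratio over members at 1 TPM or more was ranked among 10000 random lists of protein-coding genes of the same size, matched on mean expression in 20 bins. A list stood apart below the 0.5th or above the 99.5th percentile, and lists with under 3 measured members were not ranked. This describes the libraries and is no p-value. The quantifications were compared on log2(TPM + 1), and gene sums were made from transcripts present in both tables. The 2-fold count between quantifications was first run with TPM + 0.1, which gave 2654 genes, and was then set to TPM + 1, the scale of the correlations. Spike-ins were compared by their share of all counts.

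These 31 lists, the measures above except that pseudocount, and the rule for named genes were fixed before the data were examined. Further lists for skeletal muscle, liver, cAMP response and brown fat, and for day-peaking and night-peaking clock genes, were added later for the closing tests. The rule took the 20 highest nuclear protein-coding genes and the 5 highest genes of other types apart from mitochondrial ribosomal and transfer RNA, the highest members of each list, all members of the corticosteroid, zona and X-zone lists, the catecholamine enzymes and transporters, Cyp17a1, Xist and Y-linked genes. It also took the 10 highest and 10 lowest ratios among protein-coding genes and the 5 largest differences each way between quantifications. In each list that stood apart, it took the 4 members farthest in the direction of the list. A few further members, such as Dbp, Nr1d1, Arntl, Npas2, Clock, Fos and Hspa1b, were named after their values were seen. Some genes that the rule takes are not reported here.

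The steps were tested on simulated data. With known coefficients of variation of 0.1, 0.2 and 0.4 over 16564 genes, edgeR returned 0.0997, 0.196 and 0.397. Counts drawn with a coefficient of 0.1 for 22028 genes, with 4-fold and 1.5-fold changes in seeded genes, gave 94.0% of the 4-fold genes and 3.0% of the 1.5-fold genes as 2-fold apart, and 0 of 11402 unchanged ones. Of 200 random lists of 12 genes, 1 stood apart, and of 100 lists shifted by 0.3 on the log2 scale, 86 did. The coefficient of 0.1 was the same for all genes and lay below the 0.136 estimated here. The simulated lists held genes that vary independently. These rates may therefore be better than those in the real data.

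Alternatives covered thresholds, pseudocounts, count filters, TMM and DESeq2 scaling, TPM rescaled without mitochondrial genes and spike-ins, the read-derived table and leaving out each animal. A measure of the difference between the animals cannot be made from 1 animal. Allele-specific expression was not analysed here.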

Results

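Total RNA was sequenced from the adrenal glands of 2 female B6CASTF1/J mice, the first-generation cross of the C57BL/6J and CAST/EiJ strains, aged 36 days. The adrenal gland has an outer cortex that makes steroid hormones and an inner medulla that makes catecholamines. Each animal gave 1 library from 300 ng of RNA with ERCC spike-ins, synthetic RNAs of known amount, and both libraries belong to the only group of the study. The labels number the libraries as separate biological replicates but are not uniform on the animal behind each, so the SDs may measure the spread between libraries of the same animal. The deposited gene tables held 35684781 expected counts for replicate 1 and 38701795 for replicate 2. The design holds no comparison of conditions, so levels are given as mean ± SD over the animals (n = 2), and every difference below is a difference between these 2 libraries with no p-value.

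Genes of corticosteroid synthesis led the nuclear protein-coding genes of the gland. Hsd3b1, which makes progesterone from pregnenolone, stood at 4988 ± 352 TPM, and Star, which carries cholesterol into mitochondria, at 4634 ± 19.2 TPM. Cyp21a1, the 21-hydroxylase, followed at 2812 ± 23.9 TPM. Cyp11a1, the side-chain cleavage enzyme, stood at 2095 ± 121 TPM and Cyp11b1, the last step to corticosterone, at 1750 ± 58.3 TPM. Adh1, an alcohol dehydrogenase, was at 2310.5 TPM on average, and Akr1c18, a 20-alpha-hydroxysteroid dehydrogenase, at 1994.5 ± 243 TPM.

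In mm10 with GENCODE M21, Hsd3b1 (ENSMUSG00000027871.16) lies on chromosome 3 from 98852194 to 98859794, and Star (ENSMUSG00000031574.8) on chromosome 8 from 25806555 to 25815982. Cyp21a1 (ENSMUSG00000024365.9) spans 34801348 to 34804561 on chromosome 17. Cyp11b1 (ENSMUSG00000075604.5, 74834125 to 74841643) and Cyp11b2 (ENSMUSG00000022589.7, 74851010 to 74856318) are neighbours on chromosome 15. All values are totals over the annotated transcripts of a gene. The other nuclear protein-coding genes among the 20 highest were Eef1a1 (2099 TPM), Sparc (1056 TPM), Actb (999 TPM), Atp5b (931 TPM), Tpt1 (895 TPM), Fth1 (885 TPM), Rpl41 (851 TPM), Gnas (783 TPM), Akr1b7 (772 TPM), Fabp4 (769 TPM), Aldoa (768 TPM), Hba-a1 (761 TPM) and Mgst1 (726 TPM).

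Of 55536 annotated genes, 12747 reached 1 TPM in both animals, and 91.6% of these (11675) were protein-coding. Another 769 genes reached 1 TPM in only 1 of the animals, and 624 genes stood at 100 TPM or more in both. Nuclear protein-coding genes took 64.2% ± 0.175 of the expected counts but only 31.2% ± 0.0399 of the TPM. The 7SL genes Rn7s1 and Rn7s2, which encode the RNA of the signal recognition particle, stood at 157160 TPM each, and Rn7sk, a regulator of transcription elongation, at 38811 TPM. Rn7s1 and Rn7s2 held equal values in each library, so their reads cannot be assigned to either copy. With mitochondrial ribosomal RNA left out, Gm28661 at 14349 TPM and Gm26917 at 13955 TPM completed the 5 highest that are not protein-coding. Gm28661 is a pseudogene. Gm26917, annotated as a lincRNA, held 1153600 and 1517000 of the 1836395 and 2157752 lincRNA counts in replicates 1 and 2. Which RNA gave its reads was not tested. The levels of both genes are uncertain. Mitochondrial ribosomal RNA took 12.8% ± 0.485 of the counts.

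The 14 genes of the corticosteroid synthesis list were all detected, with a median of 297 TPM. Electron donors of the mitochondrial steroid enzymes were high, with Fdx1 at 652 ± 6.25 TPM and Fdxr at 373 ± 25.6 TPM, and Por, which serves the microsomal ones, stood at 90.6 ± 0.615 TPM. The steroidogenic regulator Nr5a1 was at 221 ± 2.91 TPM and Nr0b1, a repressor of it, at 7.56 ± 1.66 TPM. The corticotropin receptor Mc2r stood at 98.2 ± 4.04 TPM and its partner Mrap at 195 ± 15.8 TPM. Of the 6 genes of androgen and oestrogen synthesis, 2 were detected in both animals, Srd5a2 at 34.8 ± 4.65 TPM and Srd5a1 at 6.86 ± 0.269 TPM. Cyp17a1, needed for androgens and cortisol, was at 0.31 TPM in replicate 1 and 0.57 TPM in replicate 2, from 16 and 39 counts.

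Genes listed as zone markers of the cortex differed widely in level. Some of them, such as Cyp21a1 and Cyp11b2, are also in the corticosteroid synthesis list, so the list medians do not compare the zones themselves. The 7 markers of the zona fasciculata, the corticosterone-making zone, had a median of 620 TPM, with Abcb1b, a drug efflux pump, at 620 ± 85.8 TPM and Scarb1, the HDL receptor, at 615 ± 67.5 TPM. The 10 markers of the zona glomerulosa, the aldosterone-making zone, were all detected at a median of 18.5 TPM. Among them Dab2 stood at 136 ± 10.3 TPM, Cyp11b2, aldosterone synthase, at 66.3 ± 3.27 TPM, Agtr1a, the angiotensin receptor, at 66.3 ± 11.003 TPM and Hsd3b6 at 24.9 ± 4.43 TPM. Wnt4 was at 25.3 ± 0.919 TPM, Kcnk9 at 12.01 ± 1.19 TPM, Vsnl1 at 10.2 ± 0.509 TPM, Agtr1b at 3.61 ± 0.212 TPM, Lef1 at 3.29 ± 0.141 TPM and Shh at 3.14 ± 0.106 TPM. Cyp11b1 exceeded Cyp11b2 by 24.9 times in replicate 1 and 28.0 times in replicate 2 in the gene tables, and by 13.5 and 15.0 times in the second quantification. These related neighbours may share reads, which was not tested, so the ratio is uncertain. The X-zone is an inner cortical zone of young and female mice. Its markers beside Akr1c18 stood at 33.6 ± 2.33 TPM for Pik3c2g and 29.7 ± 1.78 TPM for Thrb.

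Markers of the adrenaline-making chromaffin cells of the medulla were detected for 26 of 27 genes, at a median of 6.68 TPM. The granule proteins Chgb and Chga were highest, at 477 ± 116 and 423 ± 59.5 TPM. Of the catecholamine enzymes, Th was at 168 ± 39.6 TPM, Pnmt, which makes adrenaline, at 131 ± 28.8 TPM, Dbh at 95.9 ± 17.2 TPM and Ddc at 16.1 ± 2.78 TPM. The vesicular transporters Slc18a1 and Slc18a2 stood at 6.68 ± 0.191 and 3.86 ± 0.163 TPM. Th (ENSMUSG00000000214.11) lies on chromosome 7 from 142892752 to 142931128, and Pnmt (ENSMUSG00000038216.7) on chromosome 11 from 98386450 to 98388181.

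**Figure D1:**
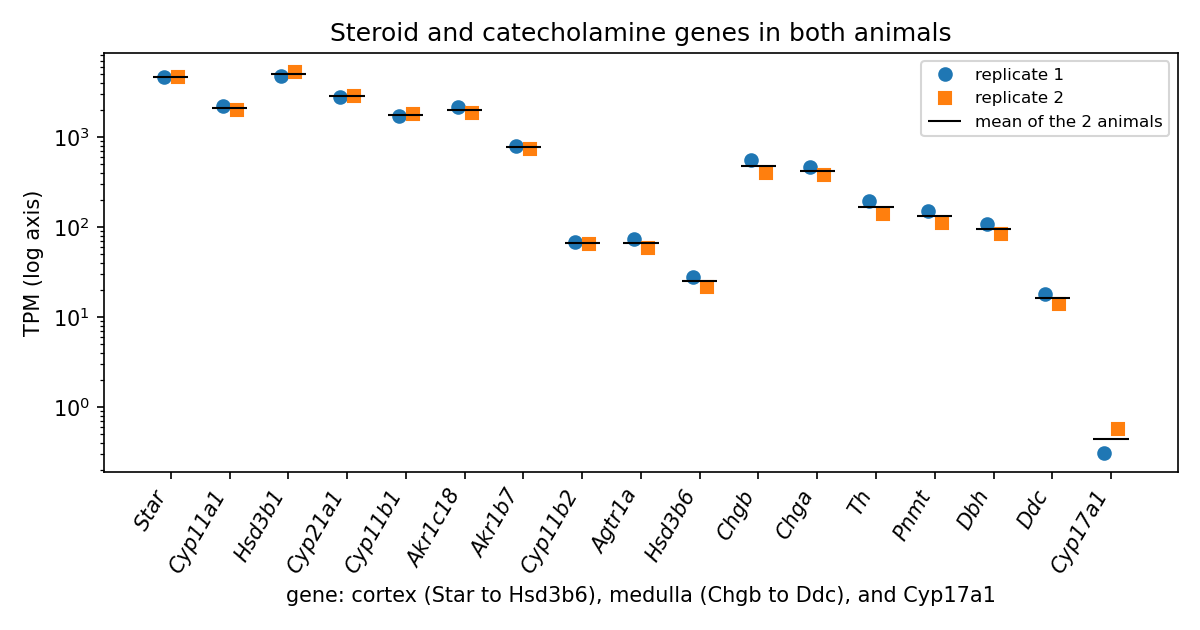
TPM (log axis) of 17 steroid and catecholamine genes in replicate 1 (circles) and replicate 2 (squares) of the female B6CASTF1/J adrenal gland, with the mean of the animals as a bar. Hsd3b1 lies at 4988 TPM on average, Star at 4634 TPM, Cyp11b2 at 66.3 TPM, the medullary enzymes Th, Pnmt and Dbh are lower in replicate 2, and Cyp17a1 lies below 1 TPM.

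Lipid supply genes were detected throughout. All 21 genes of cholesterol synthesis reached 1 TPM in both animals, at a median of 30.1 TPM, with Dhcr7 at 308 ± 27.6 TPM and Fdps at 175 ± 34.2 TPM. All 14 genes of cholesterol uptake, storage and transfer did too, at a median of 87.9 TPM, with Soat1, which esterifies cholesterol, at 319 ± 7.14 TPM and Apoe at 291 ± 13.4 TPM. The 16 nuclear respiratory chain genes had a median of 192 TPM, led by Atp5b and Cox4i1 (460 ± 7.46 TPM). The 13 mitochondrially encoded proteins had a median of 5103 TPM, with mt-Co1 at 11284 ± 655 TPM. Antioxidant genes numbered 16 of 16 at a median of 88.9 TPM, with Sod1 at 481 ± 13.3 TPM and Gpx4 at 352 ± 17.1 TPM. The 11 housekeeping genes stood at a median of 198 TPM, among them Actb and Gapdh (622 ± 7.502 TPM).

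Endothelial markers were detected for 11 of 11 genes, at a median of 13.5 TPM, with Plvap of fenestrated vessels at 60.1 ± 1.14 TPM and Egfl7 at 31.1 ± 6.93 TPM. Capsule and fibroblast markers were detected for 9 of 11 genes (median 10.6 TPM), with Col3a1 at 59.98 ± 9.58 TPM and Dcn at 55.4 ± 1.12 TPM. Pericyte and smooth muscle markers were detected for 7 of 8 (median 8.58 TPM), with Tagln at 29.0 ± 2.16 TPM and Rgs5 at 11.4 ± 0.276 TPM. Macrophage markers were detected for 9 of 10 (median 7.42 TPM), with Lyz2 at 28.7 ± 6.48 TPM and C1qa at 13.5 ± 0.163 TPM. Glial markers were detected for 2 of 9 genes, among them S100b at 3.49 ± 0.269 TPM. Lymphocyte markers were detected for 0 of 9 genes, the highest being Cd79b at 0.235 ± 0.163 TPM.

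Adipocyte markers were high in both animals, with 9 of 10 genes detected at a median of 149 TPM. Fabp4, a fatty acid carrier, stood at 769 ± 28.9 TPM and the adipokine Cfd at 450 ± 48.9 TPM. Ucp1, the uncoupling protein of brown fat (ENSMUSG00000031710.4, chromosome 8, 83290352 to 83298452), was at 320 TPM in replicate 1 and 257 TPM in replicate 2. Kidney markers were detected for 0 of 8 genes, with Aqp2 at 0.23 ± 0.0283 TPM and Lrp2 at 0.17 ± 0.0566 TPM. Of the 6 exocrine pancreas markers only Cela1 was detected, at 17.6 ± 3.02 TPM, and Ctrb1 was at 0.035 ± 0.00707 TPM.

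Cell division genes were detected for 11 of 12, at a median of 2.40 TPM, with Pcna at 27.7 ± 2.29 TPM and Mcm2 at 9.49 ± 0.990 TPM. Interferon response genes were detected for 9 of 10, at a median of 2.69 TPM, with Bst2 at 21.5 ± 2.24 TPM. Imprinted genes, expressed from 1 parental copy, were detected for 17 of 18 at a median of 15.8 TPM, led by Gnas and Cdkn1c (209 ± 19.05 TPM). Xist, expressed from the inactive X chromosome, was at 34.6 ± 3.01 TPM. Of the Y-linked genes, Ddx3y, Uty and Zfy1 were at 0 TPM in both libraries, Eif2s3y was at 0.02 TPM in replicate 1 and Kdm5d at 0.01 TPM in replicate 2. Xist was the only gene of the 7 sex-linked checks to reach 1 TPM in either animal. A count of 0 allows up to 0.0841 CPM, counts scaled to the library total, in replicate 1 and 0.0775 in replicate 2, for counting error only.

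The animals were close across most genes, and a small set stood far apart. Skeletal muscle and liver genes were higher in replicate 1. The nuclear receptor Nr4a1 and the kinase Sik1 were higher in replicate 2. Across 13516 genes at 1 TPM or more in either animal, Pearson's r of log2(TPM + 1) was 0.98 and Spearman's rho 0.98, and genes are not independent replicates. Over 12280 genes with 200 or more summed counts, the SD of the log2 ratio was 0.37.

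The biological coefficient of variation, edgeR's estimate of the spread beyond counting noise, was 0.136 over 16564 genes. The chi-square of the counts over these genes was 21.5 times its degrees of freedom, so the libraries differed by more than sampling noise and were not treated as the same library deposited again. That they came from separate animals rests on the labels alone. In all, 111 genes were 2-fold or more apart, 52 higher and 59 lower in replicate 2. Of 11612 protein-coding genes, 88 were apart, 34 higher and 54 lower. Splitting the summed counts at random gave 0 such genes in each of 100 draws. With the filter on summed counts, counting noise alone was unlikely to reach 2-fold, so a result near 0 was built in. The draws split counts, while genes were called apart on TPM, so they leave error from sharing reads between genes unmeasured. Lbhd1 was called apart with 164 and 209 counts. Among genes whose deposited TPM intervals do not overlap, 87 were apart. The count depended on the filter and pseudocount, with 298 genes at 50 or more summed counts, 1913 without a filter and 73 with TPM + 1.

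Among protein-coding genes, the 10 lowest ratios of replicate 2 over replicate 1 all belonged to genes of striated muscle. Tnnt3, fast skeletal troponin T (ENSMUSG00000061723.18, chromosome 7, 142498836 to 142516009), was at 44.5 TPM in replicate 1 and 0.12 TPM in replicate 2. Acta1, skeletal alpha-actin, was at 97.6 and 1.11 TPM, and the muscle creatine kinase Ckm at 45.9 and 0.2 TPM. The myosin heavy chains Myh1 and Myh2 were at 25.2 and 11.3 TPM in replicate 1 and at 0.06 TPM each in replicate 2. The log2 ratios, on the TPM + 0.1 scale that understates low genes, were -7.66 for Tnnt3, -7.31 for Myh1, -7.26 for Ckm, -7.08 for Atp2a1, -6.78 for Tnnc2, -6.42 for Tnni2, -6.34 for Acta1, -6.16 for Myh2, -5.98 for Ckmt2 and -5.72 for Mb. Replicate 2 held 1 count of Ckmt2, for a ratio of count shares of 407 with an exact 95% interval from 72.6 to 16100. It held 3 counts of Tnnc2, for a ratio of 223 with an interval from 75.8 to 1080.

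All 6 liver markers were higher in replicate 1. Alb, serum albumin (ENSMUSG00000029368.10, chromosome 5, 90460897 to 90476602), was at 22.7 TPM in replicate 1 and 1.34 TPM in replicate 2, and the apolipoprotein Apoa1 at 3.79 and 0.11 TPM. Only 2 of the 6 reached 1 TPM on average, so this list was not ranked in the gene tables. In the second quantification it could be ranked, with a median log2 ratio of -4.33, below all 10000 random lists.

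At the other end, Nr4a1 (ENSMUSG00000023034.7, chromosome 15, 101254269 to 101274795) was at 48.4 TPM in replicate 1 and 281 TPM in replicate 2, a log2 ratio of 2.53. Sik1, the salt-inducible kinase (ENSMUSG00000024042.7, chromosome 17, 31844250 to 31855804), was at 5.6 and 38.5 TPM, and the transcription factor Irf4 at 1.05 and 8.9 TPM. The log2 ratios were 2.97 for Irf4, 2.76 for Sik1, 2.24 for Slc25a25, 2.10 for Csrnp1, 1.62 for Gadd45b and 1.58 for Nr4a2. The other genes among the 10 highest overlap other genes and are uncertain, though overlap was not tested as the source of their ratios. They are a less abundant Nnt record, which lies inside the span of the main Nnt record on chromosome 13 and stood at 0 and 5.69 TPM, Gm20388 at 0 and 2.24 TPM, and Lbhd1 at 1.48 and 5.34 TPM, from 164 and 209 counts. In the second quantification the log2 ratio turned to -0.10 for that Nnt record and -0.19 for Lbhd1. From counts with TMM scaling, the log2 ratio of Lbhd1 was only 0.21. Both Nnt records together stood at 38.7 and 40.0 TPM.

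**Figure D2:**
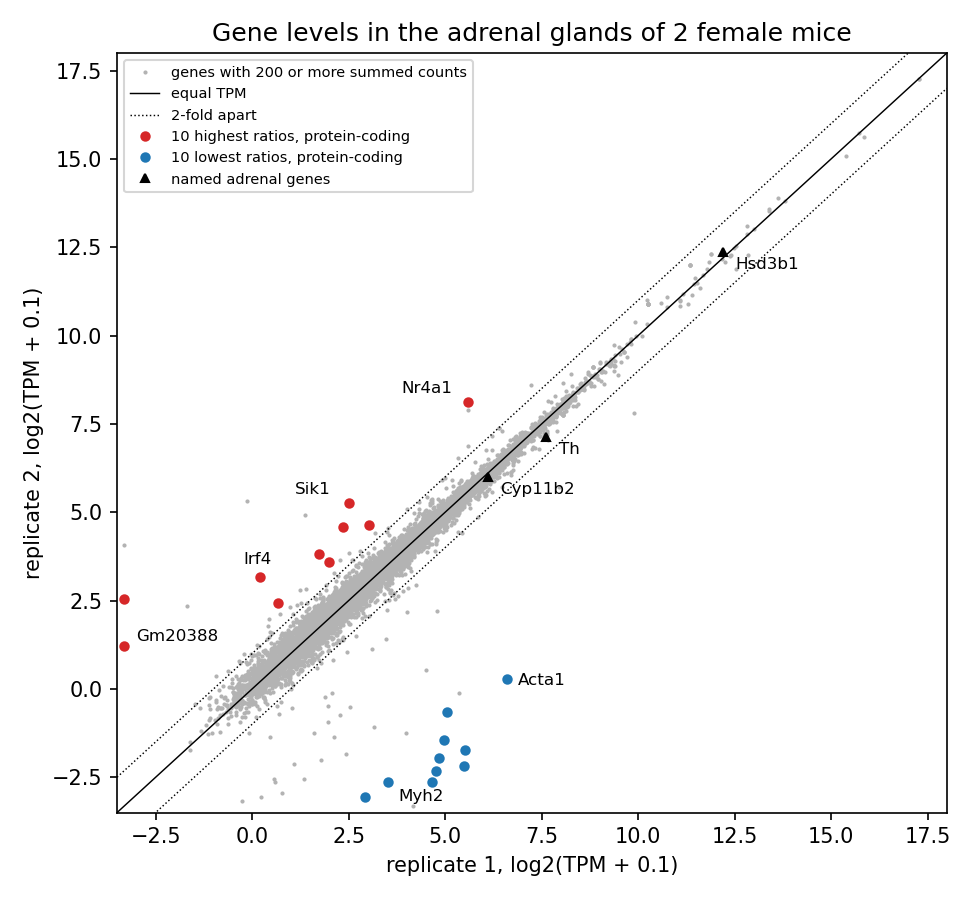
log2(TPM + 0.1) of genes with 200 or more summed counts in replicate 1 (horizontal) and replicate 2 (vertical), with lines of equality and of 2-fold difference. The 10 protein-coding genes with the lowest ratios, from -7.66 to -5.72, lie far below the lines and the 10 with the highest lie above, while Hsd3b1, Cyp11b2 and Th (triangles) lie between the lines of 2-fold difference, Th at -0.49.

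Of 31 gene lists, 24 could be ranked against random lists and 7 stood apart, 1 higher and 6 lower in replicate 2. The median log2 ratio stood apart above for clock genes, and below for genes of cholesterol synthesis, heat shock, red blood cells, chromaffin cells, glucocorticoid targets and imprinted genes. The bounds alone would set about 0.24 lists apart, and random lists ignore that genes of a list vary together. Steroid synthesis genes did not stand apart.

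The circadian clock list had a median log2 ratio of 0.39, above all 10000 random lists, with 10 of 13 ranked members higher in replicate 2. The period genes Per1 (1.09), Per3 (1.02) and Per2 (0.83) were highest by log2 ratio, then Hlf (0.59). Dbp, at 79.5 TPM in replicate 2 and 60.6 TPM in replicate 1, was also higher. Other members went the opposite way, with log2 ratios of -1.21 for Arntl, the partner of Clock, and -0.76 for Nr1d1, a repressor of the clock. Arntl was at 6.39 TPM in replicate 1 and 2.71 TPM in replicate 2, and Nr1d1 at 88.3 and 51.9 TPM. Clock was at -0.17, and Npas2, below 1 TPM on average and so not ranked, at -1.56.

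Cholesterol synthesis genes had a median log2 ratio of -0.25, below all 10000 random lists, with 18 of 21 members lower in replicate 2. Mvd (-0.67), Hmgcs1 (-0.64), Idi1 (-0.52) and Fdps (-0.40) were the farthest by log2 ratio. Hmgcs1 was at 172 TPM in replicate 1 and 110 TPM in replicate 2. Heat shock genes had a median of -0.30, below all random lists, with 6 of 9 lower. Hsph1 (-0.98), Hspa8 (-0.60), Hspb1 (-0.52) and Hsp90aa1 (-0.32) were the lowest by log2 ratio, while Hspa8 itself was at 720 and 474 TPM. The inducible Hspa1b was at 19.7 TPM in replicate 1 and 24.3 TPM in replicate 2.

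Red blood cell genes had a median log2 ratio of -0.39, at the 0.01st percentile, with 5 of 5 ranked members lower in replicate 2. Hbb-bt (-0.55), Alas2 (-0.42), Hba-a2 (-0.39) and Hba-a1 (-0.32) were the farthest. Hba-a1 and Hba-a2 are near-identical copies, as are Hspa1a and Hspa1b, so the split between copies is uncertain. Chromaffin cell genes had a median of -0.10 at the 0.1st percentile, with 22 of 26 lower. Chgb (-0.50), Th (-0.49), Cartpt (-0.48) and Npy (-0.46) were the lowest by log2 ratio. Glucocorticoid targets had a median of -0.16 at the 0.07th percentile, with 5 of 8 lower, but the members went both ways, and their median level was 19.04 TPM in replicate 1 and 23.7 TPM in replicate 2. Cdkn1a (-1.13), Fkbp5 (-0.47), Sgk1 (-0.23) and Zbtb16 (-0.21) were lower, while Per1 (1.09) and Ddit4 (1.02) were higher. Imprinted genes had a median of -0.12 at the 0.14th percentile, with 13 of 17 lower. The lowest by log2 ratio were H19 (-1.84), Igf2 (-0.45), Mirg (-0.35) and Grb10 (-0.27), although Igf2 turned to 0.05 with TMM scaling and 0.06 with DESeq2 size factors. In the second quantification the imprinted list lay at the 0.66th percentile and no longer stood apart.

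The other ranked lists lay inside the random range. Corticosteroid synthesis had a median log2 ratio of -0.01 (46.4th percentile), cholesterol uptake 0.02 (71.1th), zona glomerulosa -0.09 (2.36th), zona fasciculata -0.11 (3.32th) and X-zone 0.12 (89.4th). Immediate-early genes, which respond within minutes to stimuli, had a median of -0.11 (0.625th percentile) with members on both sides. Nr4a1 and Jun (46.0 ± 2.55 TPM) were the most abundant, and Fos was at 13.0 and 5.72 TPM. This list stood apart, lower, with TMM scaling, with log2(TPM + 1) and among members at 5 TPM or more. Capsule and fibroblasts lay at -0.14 (0.58th percentile), and stood apart only with log2(TPM + 1). The remaining medians were -0.02 for endothelium, -0.01 for pericytes and smooth muscle, -0.07 for macrophages, 0.00 for adipocytes, 0.13 for cell division, 0.16 for interferon response, 0.00 for mitochondrially encoded proteins, 0.01 for the nuclear respiratory chain, 0.01 for antioxidant defence and 0.02 for housekeeping.

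**Figure D3:**
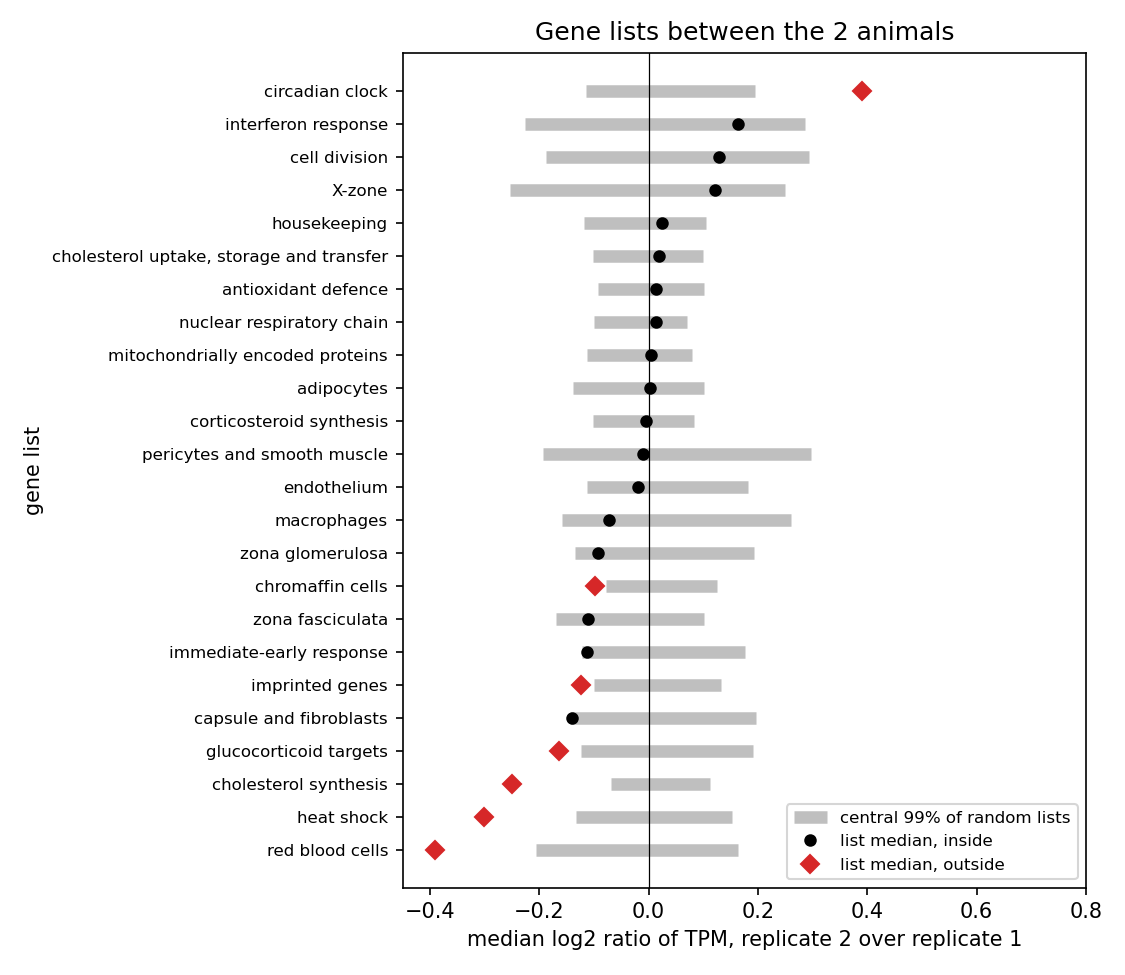
Median log2 ratio of TPM, replicate 2 over replicate 1, of 24 gene lists (points), with the central 99% of 10000 random lists of the same size and expression as bars. The 7 lists outside their bars are drawn as red diamonds, from red blood cells at -0.39 to circadian clock at 0.39.

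Spike-ins took 0.902% of the counts in replicate 1 and 0.976% in replicate 2. Over 36 spike-ins with 100 or more summed counts, the median log2 ratio of count shares, replicate 2 over replicate 1, was 0.10 with an SD of 0.17. The median over protein-coding genes was 0.02.

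The 2 quantifications of each library parted most on small RNAs and gene copies. Rn7s1, Rn7s2 and Rn7sk, at 34948 TPM or more in the alignment-derived tables, were at 2.05 TPM or less in the read-derived table. Also there, mt-Atp8, at 7350 and 4990 TPM, and Rmrp, an RNA of a ribonuclease, at 5997 and 3814 TPM, were at 0 in both libraries. In the other direction, the pseudogene Gm28439 and the gene Gm47283 were at 0 TPM in the alignment-derived tables, while Gm47283 reached 184 and 128.5 TPM in the read-derived one. Gm47283 is annotated on chromosome Y, but which chromosome gave its reads was not tested. Gm12840, Gm7336 and Hist2h2aa1 completed the 5 highest, at 728, 449 and 403 TPM in replicate 1 by the read-derived table. Genes with an effective length under 200 bases had a median fold, read-derived over alignment-derived, of 0.0258 in replicate 1 and 0.0229 in replicate 2. The longer classes had folds of 1.6 to 1.84. Small nuclear RNAs held 98642 and 151528 counts in the alignment-derived tables and 0 in the read-derived one. Pseudogenes, gene copies and overlapping genes can also share reads with other genes. The reasons were not tested, and all of these levels are uncertain.

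Protein-coding genes at 5 TPM or more were 1.70 times higher in the read-derived table in replicate 1 and 1.69 times in replicate 2, by the median. Nuclear protein-coding genes took 59.2% of the TPM in both libraries there, against 31.2% in the alignment-derived table. The median of the zona fasciculata list was 1320 TPM there. Across gene sums Pearson's r of log2(TPM + 1) was 0.95 in both libraries, with a Spearman's rho of 0.89. Across 141767 transcripts r was 0.78 in both. Of 11015 genes at 5 TPM or more in either table, 2189 differed 2-fold or more the same way in both libraries, 1840 higher and 349 lower in the read-derived table. Relative to the median ratio, an alternative chosen after seeing the data, the count was 605, 225 higher and 380 lower.

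Single main transcripts carried most steroid genes. Cyp11a1-201 took 98.6% of the gene's TPM in both animals, and Cyp21a1-201 took 98.1% in replicate 1 and 98.4% in replicate 2. Cyp11b1 and Cyp11b2 have 1 annotated transcript each. Star was split between Star-202 (52.5% and 50.8%) and Star-201. Hsd3b1-201 took 63.1% and 67.6% in the alignment-derived table but 34.3% and 40.0% in the read-derived one. Nr5a1-201 took 84.2% and 83.8% in the former and 3.80% and 12.9% in the latter. In the medulla Dbh-201 took 99.52% and 99.13%, and Th-201 100% by the alignment-derived table against 76.2% and 72.8% by the other. Of 7729 genes at 5 TPM or more with more than 1 transcript, 92.2% had the same main transcript in both animals, and 68.6% had it in both animals and both quantifications.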

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

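Counts of detected genes and of list genes stayed within 1.5 times of their values under each alternative that was run. Without one animal at a time the detected genes numbered 13125 to 13138, and the list genes 279 to 283 against 277. The correlation between the animals was 0.9579 with log2(TPM + 0.1) and 0.9941 with no filter. The biological coefficient of variation was 0.0992 with at least 100 counts in both libraries, 0.163 with all counted genes and 0.134 in the read-derived table, against 0.136. Genes 2-fold apart numbered 298 at 50 or more summed counts, 1913 without a filter and 73 with TPM + 1, against 111. Fewer counts bring more counting noise, and a larger pseudocount shrinks low genes. Added after seeing the data, the count was 106 without the liver and muscle list genes and 87 among genes whose deposited TPM intervals do not overlap. The muscle list was separate from the 10 striated muscle genes with the lowest ratios. Those genes were not dropped, so the 106 is not a count free of muscle genes. Between the quantifications 605 genes were apart relative to the median ratio, also chosen after seeing the data, against 2189. Their correlation was 0.773 over transcripts and 0.945 over genes with log2(TPM + 0.1), and 0.556 and 0.836 at 1 TPM or more in either table only. The cause was not tested. In the read-derived table the log2 ratio turned to -0.10 for the less abundant Nnt record and -0.19 for Lbhd1. With TMM scaling and DESeq2 size factors it turned to 0.05 and 0.06 for Igf2, against -0.45. Lists that stood apart numbered 7 to 9 under the alternatives, including another random seed. The 7 in the read-derived table included liver (-4.33) and not imprinted genes (-0.10). Rescaling without mitochondrial genes and spike-ins multiplied TPM by 1.23 and 1.22. With 1 library per animal, depth limits genes under about 200 summed counts.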

Other observations

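The tests of the quantifier, of depth, of dilution, of the clock and of a shared stray tissue were chosen after the results they bear on were seen, and the lists of muscle, liver, cAMP and brown fat genes were written before their values were seen.

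Genes that cAMP raises were mostly higher in replicate 2. Rgs2, a regulator of G-protein signalling, was at 88.7 TPM in replicate 1 and 159 TPM in replicate 2, Gem at 19.9 and 33.7 TPM and Crem at 38.9 and 48.4 TPM. Rgs16 went the other way, at 4.08 and 0.83 TPM. Several genes of the brown fat list were high in both glands, with Kcnk3 at 422 ± 34.9 TPM, Cox8b at 325 ± 2.27 TPM and Cox7a1 at 128 ± 8.08 TPM. Zic1, of the same list, was at 0 TPM in both. Kcnk3 stood above Ucp1 in both libraries, and whether its RNA came from brown fat or from adrenal cells cannot be told here.

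Muscle and liver genes were higher in replicate 1. Over the muscle and liver lists the median log2 ratio was -2.46 in the read-derived table. That argues against sharing of reads between related genes particular to the alignment-derived table. Both tables come from the same reads, so sharing common to both was not tested. The median was 0.0434 over 10753 protein-coding genes at 1 to 50 TPM. TPM sums to a fixed total in each library, so a median near 0 was largely built in. It cannot decide on a difference in depth or scaling. RNA of liver in that sample is a candidate source, since 14 of 17 genes of a separate liver list with 20 or more summed counts (82.4%) were 2-fold or more higher there, such as Apoa2 at 3.84 against 0.66 TPM. Against it, the 4 members at 1 TPM or more on average did not stand apart (median log2 ratio -0.19, 6.32th percentile), and Cyp2e1, the most abundant at 85.9 and 84.8 TPM, Apoc3 and Ttpa were the 3 of 18 also at 1 TPM or more in replicate 2. RNA of skeletal muscle stays open by the bound set beforehand. Of the separate muscle list, 14 of 18 genes (77.8%) were 2-fold higher in replicate 1, short of 80%. Its 10 members at 1 TPM or more on average nevertheless lay below all random lists (-1.50). Tpm2 was at 43.0 and 21.2 TPM, and Pygm at 22.8 and 23.0 TPM. In replicate 2, 7 of 20 members of the muscle list stood at 1 TPM or more, and 1 member (Cox6a2) is also in the brown fat list. The labels given to liver and muscle rest on the 80% bound alone and do not rank liver above muscle. The genes with the lowest ratios were also of striated muscle, but those genes gave the pattern.

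Nr4a1, Sik1 and clock genes differed in replicate 2. Over 19 of these genes the median absolute log2 ratio was 0.803 in the read-derived table. That argues against sharing of reads particular to the alignment-derived table, while sharing common to both tables was not tested. Dilution of replicate 1 is argued against by a median of -0.00555 over corticosteroid synthesis genes. A cAMP-driven response is a candidate explanation, with a median log2 ratio of 0.265 over the separate list (99.97th percentile, 10 of 13 members higher), although 7 of 13 immediate-early genes were lower (median -0.11), Fos among them, and that list stood apart below with TMM scaling, log2(TPM + 1) and members at 5 TPM or more. A different daily phase at collection stays open, as the gap of 2.03 between day-peaking and night-peaking clock genes came from genes already seen, left out Nr1d1, which was lower (-0.76), and the labels give no collection time. With only 1 group in the design, no explanation by a group was tested for any of these patterns.

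Brown fat genes stood high in both libraries, and the median log2 ratio of the separate list was 0.13 (99.52th percentile, 10 of 15 members higher in replicate 2), although Ucp1 and the list's median level, 31.1 and 28.6 TPM, were lower there. Ucp1 stood at 389.0 TPM or more in the read-derived table. That argues against sharing of reads particular to the alignment-derived table, while sharing common to both tables was not tested. A single stray tissue behind both the muscle and the brown fat genes is argued against by a median log2 ratio of 0.00333 over the adipocyte list. Brown fat attached to both glands is a candidate source, with 15 of 16 genes of a separate list (93.8%) at 1 TPM or more in both libraries. Of all protein-coding genes, 53% also reached that level in both, so detection alone is a weak test. Some genes of the brown fat list may also be made by adrenal cells, which these libraries cannot separate.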
